A study of Rattus norvegicus with 6 samples.

How the data were processed

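RNA from flow-sorted rat neuroepithelial progenitor cells of stage E10.5 was measured on Affymetrix arrays with a biotin label, 3 arrays from embryos of dams given oil and 3 from those of dams given retinoic acid at 60 mg/kg. Per the labels, total RNA was extracted with Trizol, and ERCC ExFold spike-in mix 1 went into control and mix 2 into retinoic acid samples. Groups and replicate numbers were taken from the sample titles.

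The deposited value table holds log2 intensities of 29656 probe sets on the 6 arrays, with no missing values, and the scale was inferred from its range. How the authors corrected background, normalized and summarized the probes is not given in the sources used here. The second deposited table holds the authors' statistics, with log2 fold changes, p-values and a log-odds score per probe set, and limma is named in the submitters' processing notes with no version. Its log2 fold changes differed from the group mean differences of the value table by at most 8.0e-09. Its 6 per-sample columns were not used. Gene symbols, Entrez identifiers and coordinates came from this table, whose genome build is not given in the sources used here.

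Of the probe sets, 29489 were main probe sets and 167 were controls, 92 of them ERCC transcripts. A gene identifier was given for 20258 main probe sets and none for 9231. The identifiers name 19634 genes, of which 18615 (94.8%) matched the reference gene table by Entrez identifier, and the symbols of 4277 genes were updated from it. For the 458 genes with over 1 probe set the one with the highest mean over all 6 arrays was used, and in 1 of these genes probe sets were called in opposite directions.

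Differences are retinoic acid minus control on the log2 scale, fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes. The threshold was an adjusted p of 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 was used for array weights. The number of arrays limits the precision.

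Before the data were examined, 26 pathway and regional lists and 10 lists of cell type markers were fixed, with 644 genes, of which 52 were not matched. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 36 lists, with an estimated correlation as an alternative. That alternative also rests on the 4 residual degrees of freedom of the fit, so it is stricter even where the estimate is low. The estimate was -0.13 for the Zic list and -0.02 for mesoderm markers, below the preset, and both lost their call. Losing a call there is thus no sign by itself of correlated genes. Some genes belong to several lists. Each list's members were also counted after adjustment over the list alone. The rule for named genes was fixed then too. It took the 10 largest increases and decreases among called genes with non-overlapping groups, up to 2 rising and 2 falling members per list by smallest p, and a fixed set of retinoic acid, Zic, COUP-TF, Gli and TGF-beta genes, 108 genes in all. Genes known only by a LOC or RGD number were skipped among the largest increases and decreases. Pmepa1 was named outside this rule, after its value was seen, to complete a count of 4.

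The test was checked on simulated data with the spread of these arrays, in 20 draws of 19634 genes with 200 changed. It recovered 79% of genes changed by 0.5 and 99.2% of those changed by 1 on the log2 scale, and 4.10% of its calls were unchanged genes. A list shifted by 0.15 was found in 20 of the 20 draws, in separate simulated arrays where no other gene was changed. The draws changed far fewer genes than the 1900 called in the real data, and recovery at that share was not tested. The simulated genes varied independently of each other, whereas estimated correlations within the real lists reached 0.45. How often lists of correlated genes are found, or called wrongly, was not tested by these draws.

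Alternatives fixed beforehand were other variance priors, quantile normalization, centring on the array median or on spike-in subgroup B, leaving out the dimmest 30% of genes, other rules for probe sets, a 1.5-fold threshold, array weights, a replicate block, per-gene variance without shrinkage, fry for the lists, and leaving out each array in turn. Cyclic loess, leaving out histone genes, leaving marker genes out of the pathway lists, and median centring for the lists were added after the data were seen. Probe sets with no gene identifier were left out of the gene test. Some results on single genes, and the member counts of the Zic list, are not reported here.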

Results

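Neuroepithelial progenitor cells, the dividing cells of the neural plate and neural tube, were flow sorted from rat embryos at the stage E10.5. The dams had been given all-trans retinoic acid at 60 mg/kg by gavage in olive oil, or the oil alone. Retinoic acid is the active derivative of vitamin A and patterns the embryonic nervous system, and an excess of it in pregnancy disturbs closure of the neural tube. RNA from 3 control and 3 retinoic acid samples was read on Affymetrix arrays, and each sample was a pool of biological replicates. The number of animals in a pool was not given in the sources used here, and the p-values below measure only the spread between these pooled samples. The median log2 intensity over all probe sets lay between 6.29 and 6.39 on the 6 arrays. Across genes, which are not independent replicates, the Pearson correlation was 0.996 to 0.997 between arrays of a group and 0.994 to 0.995 between arrays of different groups. The first principal component held 48.6% of the variance and separated the groups. The title of the series names TGF-beta, COUP-TFII and the Gli1 and Zic transcription factors in a neural tube defect induced by retinoic acid, so the question was how these and related genes differed between the groups.

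In the retinoic acid samples Zic2, a transcription factor needed for closure of the neural tube, rose by 0.89 on the log2 scale (SE 0.07, adjusted p = 6.0e-07 by limma, n = 3 per group). The progenitor factor Sox2 rose by 0.83 and the dorsal factor Pax3 by 0.76. The lists of cholesterol synthesis and of glycolysis were higher by camera in limma at its preset correlation, with medians of 0.39 and 0.34. They did not pass camera with an estimated correlation (adjusted p = 0.0720 and adjusted p = 0.0689). Markers of endothelium fell, with a median of -0.36, and markers of heart muscle rose, with a median of 0.46. The genes for COUP-TFII (Nr2f2), Gli1 and the 3 TGF-beta ligands did not pass the test.

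Of 19634 genes tested, 1900 (9.68%) passed the threshold, 1495 higher and 405 lower in the retinoic acid samples (78.7% higher). The median log2 difference over all genes was 0.03 and the median size among the called genes was 0.31. Only 75 of the higher and 25 of the lower genes differed by 1.5-fold or more, and 6 and 2 by 2-fold or more. The median SD between arrays of a group was 0.07 in control and 0.08 in retinoic acid. The groups did not overlap in 1889 of the called genes and in 5105 of all genes, where chance gives 10%. Without control replicate 3 the counts were 894 higher and 292 lower, and without retinoic acid replicate 2 they were 973 and 348. Without control replicate 1 or 2 the number lower was 251. The split between higher and lower calls moved with the scaling: it was 1051 to 638 (62.2% higher) after quantile normalization, 855 to 696 (55.1%) after cyclic loess, which was added after the data were seen, and 337 to 23 (93.6%) after centring on the spike-ins of equal amount, which put the median of all genes at 0.13. Of the 97 called genes that are named, 53 kept their call after that centring, whose spike-in medians had an SD of 0.15 between replicates. Centring on the spike-ins enlarged rises (Etv4 from 0.35 to 0.44) and reduced falls (Afp from -0.33 to -0.23). Among these 97, the genes named below that did not keep their call were Afp, Bmp4, Dcn, Etv4, Gbx2, Gmnn, Hbe1, Hhip, Hoxa6, Hoxb9, Isl1, Lhx2, Msgn1, Onecut2, Pcna, Plk2, Shh, Sparc, Tgfbi, Tgfbr2, Wnt5a and Zic1. Called genes named below outside the 97, such as Pmepa1 and Fos, were not followed under this centring. Among the brighter genes the difference grew with brightness. In the brightest of 10 equal groups of genes the median was 0.16, with 603 genes higher and 18 lower, and in the group numbered 4 it was -0.00021, with 36 and 27, while the dimmest group had 0.055, with 12 and 2.

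**Figure D1:**
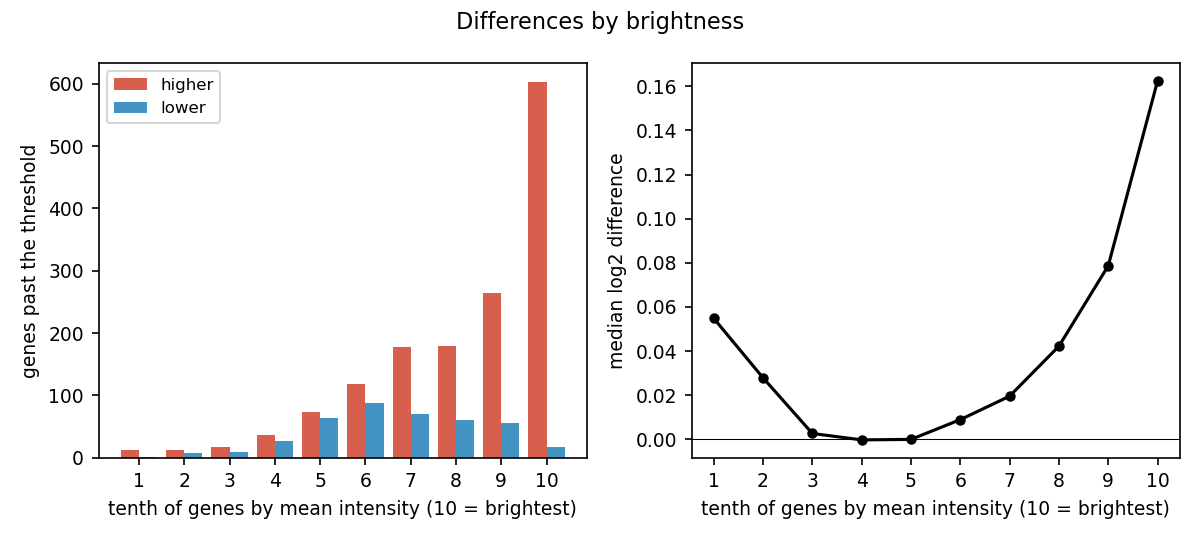
Genes are divided into 10 equal groups by mean intensity over the 6 arrays (horizontal axis, 10 is brightest). Bars count genes past the limma threshold that were higher (red) or lower (blue) with retinoic acid, and the line gives the median log2 difference of each group, which reached 0.16 in the brightest.

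Genes that retinoic acid is known to induce rose in part. Of 17 measured members of the target list, 5 rose and none fell, and the count adjusted over the list alone was also 5. Hoxb1, a hindbrain Hox gene with retinoic acid response elements, rose by 0.52 (SE 0.07, adjusted p = 1.2e-04 by limma). Cyp26a1, which breaks retinoic acid down, went from 7.18 ± 0.12 to 7.63 ± 0.11 (log2 intensity, SD, n = 3 each), and Stra6, a retinol transporter, from 9.55 ± 0.05 to 9.98 ± 0.05. Rarb, a receptor gene often used as a readout of retinoic acid, differed by -0.03 (SE 0.08, adjusted p = 0.895 by limma). The list as a whole was higher by camera in limma (adjusted p = 0.0390), but not with an estimated correlation (adjusted p = 0.190 with an estimated correlation), after quantile normalization (adjusted p = 0.141), after cyclic loess (adjusted p = 0.157), without the dimmest 30% of genes (adjusted p = 0.0584), or without control replicate 3 (adjusted p = 0.0650), retinoic acid replicate 2 (0.0582) or retinoic acid replicate 3 (0.0631). Over its alternatives by camera the adjusted p ran from 0.0235 to 0.190, and fry, which tests a list against no change rather than against other genes, gave 0.00161.

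Among 15 genes for retinoid synthesis and receptors, 1 rose and none fell, over all genes and adjusted over the list alone. It was Aldh1a2, the main retinoic acid synthesizing enzyme of the early embryo, which rose by 0.54 (SE 0.07), and the list did not pass camera (adjusted p = 0.909). Of the 11 measured Hox genes of paralogue groups 1 to 4, which are expressed in the hindbrain, 2 rose, Hoxb1 among them, and none fell, against 3 higher and 1 lower adjusted over the list alone, and camera gave an adjusted p of 0.472. Of the 18 Hox genes of groups 5 to 13, which pattern the trunk, 5 fell and 1 rose, against 7 and 1 adjusted over the list alone. Hoxd10 fell by 0.60 (SE 0.08) and Hoxa6 by 0.57 (SE 0.10), while Hoxb9 rose by 0.38 (SE 0.07). This list was lower by camera in limma (adjusted p = 4.8e-05, adjusted p = 0.190 with an estimated correlation, and 0.0520 by fry).

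**Figure D2:**
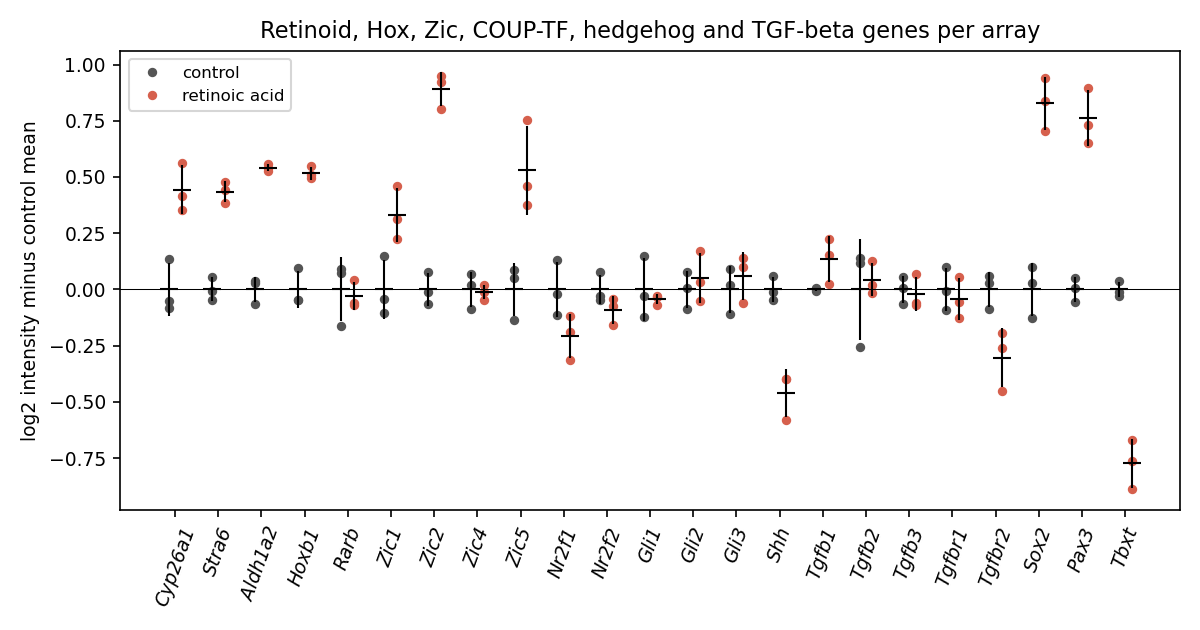
Log2 intensity of named genes on each of the 6 arrays, minus the control mean of the gene (vertical axis). Points are single arrays, grey for control and red for retinoic acid, and bars give the group mean and SD. Zic2 lies apart from its controls by 0.89, while Gli1, Gli2, Gli3, Nr2f2 and the Tgfb ligand genes differ from them by at most 0.134 in their means.

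Zic genes, which encode zinc finger factors of the dorsal neural tube, were higher as a list. Zic2 (Entrez 361096, chromosome 15, 107608819 to 107613644, on a build not given in the sources used here) went from 8.66 ± 0.07 to 9.55 ± 0.08 (log2 intensity, SD, n = 3 each). Its neighbour Zic5 (chromosome 15, 107592742 to 107598927) rose by 0.53 (SE 0.09, adjusted p = 0.00105 by limma). Zic1 rose by 0.33 (SE 0.08, adjusted p = 0.0136 by limma), and Zic4 differed by -0.01 (SE 0.07). The list was higher by camera in limma (adjusted p = 2.8e-04, and adjusted p = 0.0811 with an estimated correlation). The call for Zic1 was lost without control replicate 3 (adjusted p = 0.0745) or retinoic acid replicate 2 (0.0635) and after centring on the spike-ins (0.117), within a range of 0.00306 to 0.238 over its alternatives.

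COUP-TF genes, which encode orphan nuclear receptors, did not pass the test. Nr2f2, the gene for COUP-TFII, stood at 9.45 ± 0.07 in control and 9.36 ± 0.06 in retinoic acid (log2 intensity, SD, n = 3 each), a difference of -0.09 (SE 0.07, adjusted p = 0.50 by limma). Nr2f1 differed by -0.21 (SE 0.08, adjusted p = 0.112 by limma), with all 3 retinoic acid arrays below all 3 controls. Of the 3 measured members none passed over all genes and 1 was lower adjusted over the list alone, and camera gave an adjusted p of 0.354. A difference of the size seen for Nr2f1 was smaller than those tested on simulated data, where 79% of changes of 0.5 were found.

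In the hedgehog pathway 2 of 14 measured genes fell and none rose, over all genes and adjusted over the list alone. Shh, the ligand made by notochord and floor plate, fell by 0.46 (SE 0.07, adjusted p = 5.4e-04 by limma). Hhip, a hedgehog-binding inhibitor that the pathway induces, fell by 0.29 (SE 0.08, adjusted p = 0.0260 by limma), a call lost without control replicate 1 (adjusted p = 0.117), control replicate 2 (0.0932) or retinoic acid replicate 3 (0.131), after median centring (0.0795) and after centring on the spike-ins (0.622), within a range of 0.00455 to 0.622 over its alternatives. The transcription factor genes Gli1, Gli2 and Gli3 differed by -0.04, 0.05 and 0.06 (SE 0.08 each) and did not pass the test, and Gli1 stood at 0.053 after centring on the spike-ins, Gli2 at -0.0082 and Gli3 at -0.064 after cyclic loess. The list gave an adjusted p of 0.140 by camera. In the same samples the notochord and floor plate markers moved too, in a list that also holds Shh. Of 9 measured, 2 fell and 1 rose, against 3 and 1 adjusted over the list alone. The 2 that fell were Shh, with the value given above, and Tbxt. Tbxt, the mesoderm and notochord factor also called T or brachyury, fell by 0.77 (SE 0.07). That list was lower by camera in limma (adjusted p = 0.0145, and adjusted p = 0.181 with an estimated correlation), and not after quantile normalization (adjusted p = 0.0844), cyclic loess (0.0869) or leaving out the dimmest 30% of genes (0.0558, in a range of 0.00950 to 0.181 by camera, and 0.00533 by fry).

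Genes of the TGF-beta, activin and nodal pathway fell or did not pass the test. Of 32 measured, 4 fell and none rose, over all genes and adjusted over the list alone. They were the receptor gene Tgfbr2, the matrix proteins Tgfbi and Dcn, and Pmepa1, an inhibitor that the pathway induces. Tgfbi fell by 0.38 (SE 0.07) and Dcn by 0.42 (SE 0.08), calls lost after centring on the spike-ins (adjusted p = 0.440 and 0.333). Tgfbr2 fell by 0.30 (SE 0.08, adjusted p = 0.0177 by limma), a call lost without control replicate 2 (adjusted p = 0.0808), control replicate 3 (0.0644) or retinoic acid replicate 2 (0.0792) and after centring on the spike-ins (0.607), within a range of 0.00970 to 0.607 over its alternatives. The ligand genes Tgfb1, Tgfb2 and Tgfb3 differed by 0.13, 0.04 and -0.02 (SE 0.07, 0.09 and 0.07) and the receptor gene Tgfbr1 by -0.04 (SE 0.07), none past the threshold. The list median was -0.02, and camera in limma gave an adjusted p of 0.0493 (adjusted p = 0.195 with an estimated correlation, 0.0844 after quantile normalization, 0.0847 after cyclic loess, 0.0506 after median centring, 0.0553 without the dimmest 30% of genes and 0.294 by fry). The call was also lost without control replicate 1 (0.0638) or 2 (0.176) or retinoic acid replicate 1 (0.0760) or 2 (0.0629), within a range of 0.0115 to 0.195 by camera. Endothelial and mesenchymal markers were lower in the same samples, with list medians of -0.36 and -0.16.

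Other signalling pathways moved in part. Of 28 BMP pathway genes, 8 rose and 1 fell, against 10 and 1 adjusted over the list alone. Id1, an inhibitor of differentiation that BMP signals induce, rose by 0.70 (SE 0.08) and the homeobox gene Msx1 by 0.61 (SE 0.07), while the ligand gene Bmp4 fell by 0.37 (SE 0.07), a call lost after centring on the spike-ins (adjusted p = 0.467). The list was higher by camera in limma (adjusted p = 0.0394, and adjusted p = 0.435 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0884), after cyclic loess (0.0835), without the dimmest 30% of genes (0.102) or without control replicate 3 (0.119) or retinoic acid replicate 2 (0.143), within a range of 0.00868 to 0.435 over its alternatives. Of 22 FGF pathway genes, 5 rose and none fell, against 7 and none adjusted over the list alone. Fgf19, listed as Fgf15 in the files, rose by 1.07 (SE 0.07), and Etv4, a target of FGF signals, by 0.35 (SE 0.07). This list was higher by camera in limma (adjusted p = 0.0136, and adjusted p = 0.229 with an estimated correlation). Of 34 Wnt pathway genes, 4 rose and 3 fell, against 7 and 3 adjusted over the list alone. Sfrp5, a secreted Wnt inhibitor, rose by 0.48 (SE 0.08) and Wnt5a fell by 0.32 (SE 0.07), and camera gave an adjusted p of 0.914. Of 18 Notch pathway genes, 3 rose and 1 fell, against 3 and 3 adjusted over the list alone, with an adjusted p of 0.127 by camera.

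Markers of neural progenitors rose in part. Of 17 progenitor markers, 6 rose and none fell, over all genes and adjusted over the list alone. Sox2 went from 8.17 ± 0.12 to 8.99 ± 0.12 (log2 intensity, SD, n = 3 each) and Pax6, a factor of forebrain and spinal progenitors, rose by 0.42 (SE 0.07). The list was higher by camera in limma (adjusted p = 0.0136, and adjusted p = 0.332 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0909), after cyclic loess (0.206) or without control replicate 3 (0.0593) or retinoic acid replicate 2 (0.0629), within a range of 0.00228 to 0.332 over its alternatives. Of 25 genes of neurogenesis and early neurons, 1 rose and 2 fell, over all genes and adjusted over the list alone. Isl1, a factor of motor and sensory neurons, fell by 0.40 (SE 0.08) and Onecut2 rose by 0.30 (SE 0.07), with an adjusted p of 0.638 by camera. The difference between these lists was not tested, and their medians of 0.12 and 0.02 changed order after quantile normalization (0.026 and 0.035) and cyclic loess (0.0035 and 0.024).

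Regional genes changed in both directions. In the dorsal neural tube list 7 of 16 rose and 1 fell, over all genes and adjusted over the list alone. Zic1, Zic2 and Msx1 among the rises, and Bmp4, the fall, belong also to the Zic or BMP lists, so these lists are not independent. Pax3, which is needed for neural tube closure and neural crest, rose by 0.76 (SE 0.07, adjusted p = 6.1e-06 by limma). Camera in limma put this list higher (adjusted p = 0.0182, adjusted p = 0.190 with an estimated correlation, and 0.0514 without the dimmest 30% of genes, in a range of 0.00343 to 0.190 by camera, and 0.00326 by fry). In the ventral list 3 of 12 rose and 1 fell, against 4 and 1 adjusted over the list alone. The floor plate guidance cue Ntn1 rose by 0.81 (SE 0.08) and the progenitor factor Nkx6-1 by 0.42 (SE 0.08), whereas Shh fell, and camera gave an adjusted p of 0.463. Of 25 forebrain and midbrain genes, 3 rose and 2 fell, against 4 and 2 adjusted over the list alone. The forebrain factors Lhx9 and Lhx2 fell by 0.63 and 0.47 (SE 0.07 each) and Pax8 rose by 0.51 (SE 0.07), with an adjusted p of 0.907 by camera. Of 13 hindbrain and spinal cord genes, 3 rose and 2 fell, against 3 and 3 adjusted over the list alone. Egr2, a factor of hindbrain rhombomeres and also an immediate early gene, rose by 0.75 (SE 0.07) and Gbx2, a gene of the midbrain and hindbrain border, by 0.36 (SE 0.07), while Tbxt fell, with an adjusted p of 0.914 by camera. For the last 2 lists, and for those of neurogenesis and p53 targets, the median lay above 0 while camera, which compares with all other genes, pointed down. The medians of the forebrain and midbrain list (0.08) and of p53 targets (0.05) lay also above that of all genes (0.03). Why camera pointed down for them was not tested.

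Of 25 genes for planar cell polarity and neural tube closure, 8 rose and none fell, against 12 and none adjusted over the list alone. Grhl3, a surface ectoderm factor needed for spinal closure, rose by 0.48 (SE 0.07) and Tfap2a, a factor of neural crest and ectoderm, by 0.40 (SE 0.08). Both belong to the ectoderm beside the neural plate rather than to planar cell polarity. The list was higher by camera in limma (adjusted p = 2.1e-04, and adjusted p = 0.211 with an estimated correlation). Markers of the neighbouring surface ectoderm stood higher in 3 of 13 genes and lower in none, against 5 and none adjusted over the list alone, among them the splicing factor Esrp1 at 0.50 (SE 0.07), and that list gave an adjusted p of 0.0510 by camera, but passed without control replicate 1 (0.0320) or 3 (0.0411) or retinoic acid replicate 1 (0.0469), in a range of 0.0320 to 0.195 by camera, and 0.00627 by fry. Placode markers rose in 6 of 10 genes and fell in none, against 7 and none adjusted over the list alone, with Dlx5 at 0.40 (SE 0.07) and Pax8 at 0.51 (camera adjusted p = 1.5e-04 in limma, and adjusted p = 0.0720 with an estimated correlation). Of 13 neural crest markers, 3 rose and 1 fell, against 4 and 2 adjusted over the list alone, with Dlx2 at 0.43 (SE 0.08) and an adjusted p of 0.263 by camera and 0.0244 by fry.

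Metabolic genes rose, with none lower in either list. Of 20 cholesterol synthesis genes, 16 rose and none fell, against 19 and none adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, went from 9.81 ± 0.08 to 10.46 ± 0.06 (log2 intensity, SD, n = 3 each) and the sterol oxidase Msmo1 rose by 0.74 (SE 0.08). Camera in limma put the list higher (adjusted p = 7.0e-19, and adjusted p = 0.0720 with an estimated correlation). Of 19 glycolysis and hypoxia genes, 11 rose and none fell, against 13 and none adjusted over the list alone. The mitochondrial hypoxia target Bnip3 rose by 0.72 (SE 0.07) and the glycolytic enzyme gene Pfkl by 0.65 (SE 0.07). This list was also higher by camera in limma (adjusted p = 1.2e-09, and adjusted p = 0.0689 with an estimated correlation). Its median of 0.34 was 0.20 after quantile normalization and 0.19 after cyclic loess.

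Cell cycle and stress genes moved in part. Of 24 S phase genes, 7 rose and none fell, against 13 and none adjusted over the list alone. Gmnn, which limits DNA replication to a single round per cycle, rose by 0.33 (SE 0.07), and Pcna, the clamp of DNA polymerases, by 0.38 (SE 0.07), a call that was lost after cyclic loess (0.13, adjusted p = 0.205 by limma, in a range of 7.4e-04 to 0.205 over its alternatives). The list was higher by camera in limma (adjusted p = 5.4e-05, and adjusted p = 0.185 with an estimated correlation), but not after cyclic loess (adjusted p = 0.0775, in a range of 1.7e-05 to 0.185). Of 23 G2 and M phase genes, 2 rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0517). That list passed without control replicate 1 (0.0165) or 2 (0.0142) or retinoic acid replicate 1 (0.0144) or 3 (0.0232) and with a replicate block (0.0431), in a range of 0.0142 to 0.652, and its median of 0.11 turned to -0.02 after cyclic loess. Of 23 p53 target and apoptosis genes, 3 rose and 2 fell, over all genes and adjusted over the list alone. Btg2, an antiproliferative gene that is also an immediate early gene, rose by 0.88 (SE 0.07) and the kinase gene Plk2 fell by 0.41 (SE 0.07), with an adjusted p of 0.925 by camera. Of 17 unfolded protein response genes, 5 rose and none fell, against 6 and 1 adjusted over the list alone, with the stress factor Atf3 at 0.56 (SE 0.07) and an adjusted p of 0.166 by camera. Of 16 genes of extracellular matrix and basement membrane, 1 rose and 2 fell, against 2 and 3 adjusted over the list alone. Sparc, a secreted matrix glycoprotein, fell by 0.49 (SE 0.08), and the list gave an adjusted p of 0.0517 by camera. It passed after quantile normalization (0.00190) and cyclic loess (3.0e-04), with a replicate block (0.0431) and without control replicate 1 (0.0408) or 3 (0.00731) or retinoic acid replicate 2 (0.0214), in a range of 3.0e-04 to 0.650 over its alternatives.

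Markers of cell types other than the sorted progenitors differed between the groups. Of 12 endothelial markers, 10 fell and none rose, against 11 and none adjusted over the list alone. The endothelial cadherin gene Cdh5 went from 9.58 ± 0.06 to 8.80 ± 0.10 (log2 intensity, SD, n = 3 each) and the factor Erg fell by 0.63 (SE 0.07). Of 9 heart muscle markers, 7 rose and none fell, against 8 and none adjusted over the list alone. Myl7, an atrial myosin light chain, went from 6.35 ± 0.05 to 8.17 ± 0.05 and Actc1, cardiac actin, from 7.68 ± 0.07 to 9.15 ± 0.08 (log2 intensity, SD, n = 3 each). These 2 lists were the only ones of the 36 to pass camera in limma with an estimated correlation as well (adjusted p = 0.0254 for endothelium and 0.0496 for heart muscle).

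Mesoderm and mesenchyme markers fell in 8 and rose in 5 of 22 genes, against 11 and 5 adjusted over the list alone. The collagen gene Col1a1 fell by 0.71 (SE 0.09) and Msgn1, a factor of presomitic mesoderm, by 0.53 (SE 0.07), while the somite factor Meox1 rose by 0.93 (SE 0.07). That list was lower by camera in limma (adjusted p = 1.6e-04, and adjusted p = 0.0720 with an estimated correlation). Of 11 erythroid markers, 4 rose and none fell, against 5 and none adjusted over the list alone (camera adjusted p = 0.00790 in limma, adjusted p = 0.299 with an estimated correlation, 0.189 after quantile normalization and 0.296 after cyclic loess, in a range of 8.3e-04 to 0.299). The embryonic globin gene Hbe1 stood at 13.58 ± 0.12 in control and 13.97 ± 0.07 in retinoic acid (log2 intensity, SD, n = 3 each), and its difference of 0.38 was 0.00057 after cyclic loess (adjusted p = 0.997 by limma, in a range of 0.00143 to 0.997). Of 16 endoderm and yolk sac markers, 2 fell and none rose, over all genes and adjusted over the list alone. The fetal serum protein gene Afp fell by 0.33 (SE 0.07), a call lost after centring on the spike-ins (adjusted p = 0.559), and the list was lower by camera in limma (adjusted p = 0.0174, adjusted p = 0.181 with an estimated correlation, 0.0909 after quantile normalization and 0.0906 after cyclic loess, in a range of 0.0134 to 0.181). Of 14 leukocyte markers, 1 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.797).

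**Figure D3:**
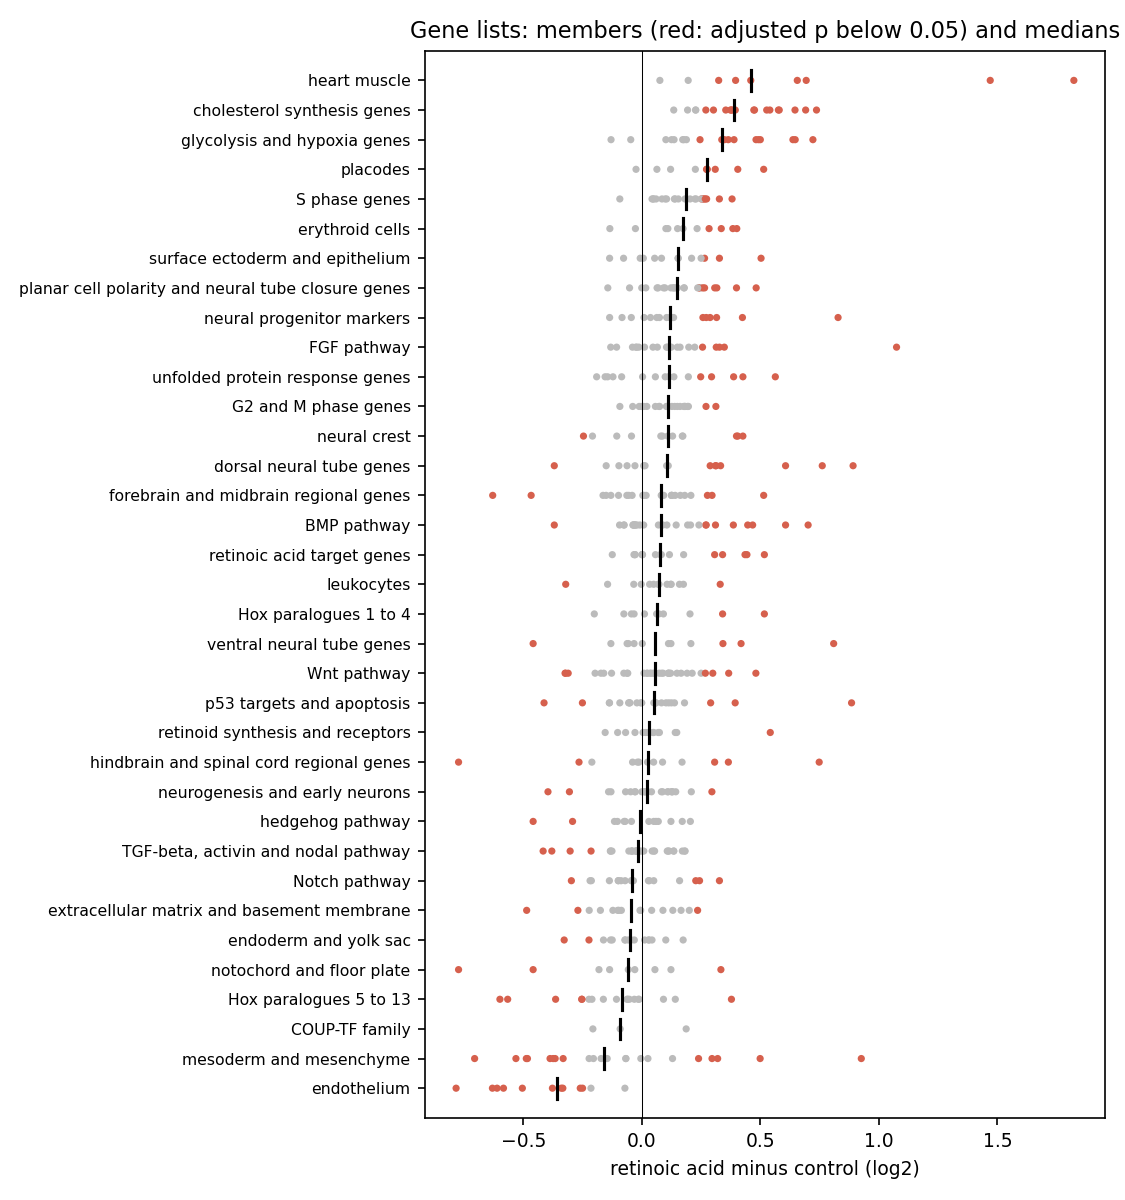
Log2 difference between retinoic acid and control (horizontal axis) for each measured member of the gene lists other than the Zic family. Points are genes, red where limma gave an adjusted p below 0.05, and the black bar is the list median, from -0.36 for endothelium to 0.46 for heart muscle.

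In total 19 of the 36 lists passed camera with its preset correlation, 13 higher and 6 lower, and 2 passed with an estimated correlation.

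Genes known only by a LOC or RGD number were left out of the rankings that follow. The 10 largest increases among genes with non-overlapping groups were led by Hist1h2bb at 2.75 (SE 0.07, adjusted p = 3.9e-14 by limma), a replication-dependent histone gene with near-identical copies, so its probe set could be shared with them. Next came Myl7 at 1.82, Actc1 at 1.47, the calcium-binding protein gene S100a1 at 1.12 and the immediate early nuclear receptor gene Nr4a1 at 1.10. They were followed by Fgf19, the ribosomal protein gene Rpl10 at 0.96, Meox1, the histone-like gene H2bcl1 at 0.91 and Zic2. The largest decreases were led by the olfactory receptor gene Or8h7b at -1.55 (SE 0.08, adjusted p = 1.1e-09 by limma), whose control level of 12.21 is bright for a receptor of the nasal epithelium, so what its probe set reads is uncertain. After it came the histone-like H2az2l2 at -1.24, C1h9orf85 at -0.84, Cdh5 at -0.78, the catalase gene Cat at -0.78 and Tbxt at -0.77. The chemokine gene Cxcl13 followed at -0.76, the factor Nfib at -0.74, the orphan receptor gene Gpr50 at -0.73 and the GABA receptor gene Gabrg3 at -0.71.

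External RNA controls tested the labels and the scale of the differences. ERCC ExFold mixes hold the same synthetic transcripts in 4 subgroups of known ratio, with mix 1 in the control and mix 2 in the retinoic acid samples. All 4 medians over 23 transcripts each went in the nominal direction or lay near 0 where no difference was due: -0.50 for subgroup A (nominal -2), -0.0022 for B (nominal 0), 0.21 for C (nominal 0.58) and 0.42 for D (nominal 1). Between 7 and 11 in mean log2 intensity the medians were -1.60, -0.18, 0.30 and 0.50, and subgroup A reached -0.17 below 7 and -0.96 above 11, so its differences were compressed for dim and for the brightest transcripts. Single transcripts of subgroup B ranged from -0.46 to 0.17. Control replicate 3 weighed on these values: without it the medians of C and D were 0.04 and 0.17, and without control replicate 2 those of A and C were -0.30 and 0.32.

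**Figure D4:**
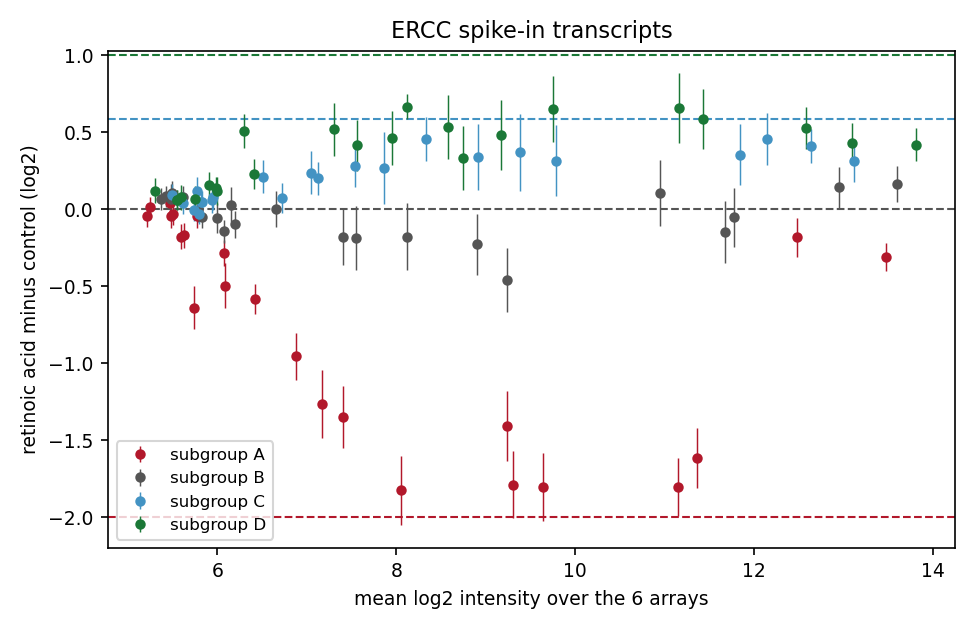
Log2 difference between retinoic acid and control (vertical axis) for ERCC spike-in transcripts against their mean log2 intensity over the 6 arrays (horizontal axis). Points are transcripts coloured by subgroup, bars are limma standard errors and dashed lines are the nominal ratios, which the medians of -1.60, -0.18, 0.30 and 0.50 between 7 and 11 did not reach for A, C and D.

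In the authors' deposited table of statistics 2320 probe sets passed an adjusted p of 0.05, 1497 higher and 823 lower. Its p-values differed by at most 6.9e-08 from a limma fit to all probe sets, controls included. Of the 1900 genes called here, 1494 were also called by their probe set in the authors' deposited table, which adjusts over all probe sets.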

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

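The test of a lower share of sorted progenitors and those of an intensity-dependent difference (also for histones) and of the hybridization controls were chosen after the results were seen. Further heart muscle and endothelial genes were chosen with the pattern known but before their own values were seen. The tests of a scaling offset, of falls hidden at the background, of S phase and of shared histone probe sets were written before their values were seen.

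Probe sets with no gene identifier lie outside the gene comparison, and 230 of the 9231 were higher in retinoic acid by limma while 496 were lower. After cyclic loess these counts were 145 and 541. Of the 75 control probe sets other than ERCC transcripts, which report bacterial RNAs added during preparation, 17 were higher and 0 lower by limma, among them 6 dap probe sets at 0.47 to 0.76.

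More genes rose than fell. An offset of each array common to all probe sets is argued against, since 82.2% of called genes stayed higher after median centring (67.7 to 87.5% with an array left out). That centring moved the median of all genes from 0.03 to 0.05. Quantile normalization put it at 0.01 and gave 62.2% higher. Falls hidden at the background are argued against only among the brightest 25% of genes, where 90.9% were higher (85.3 to 92.7%). The difference that grew with brightness was largest there, so this share does not speak for dimmer genes. An intensity-dependent difference between the arrays may account for the excess, as the share was 55.1% after cyclic loess (52.3 to 57.5% with an array left out). Cyclic loess removes a shift that follows brightness whatever its source, so this share cannot tell a technical source from one in the cells. The 18 hybridization control probe sets read the RNAs bioB, bioC, bioD and cre, added in equal amounts to each sample. All 18 were higher in mean, with a median of 0.29 (0.19 to 0.40 with an array left out). The 2408 genes between the dimmest and the brightest of them had a median of 0.15. These genes were not matched to the controls in brightness within that range. The medians of the controls ran from 0.22 for the dimmest, bioB, to 0.42 for the brightest, cre, so the 2 medians are not a like comparison. The 18 control probe sets are not independent, and the groups overlapped in part. Control replicate 2 lay above retinoic acid replicate 1 for bioB (9.77 against 9.66), bioC (10.70 against 10.56) and bioD (12.17 against 12.09). The 5 spike-ins of equal amount in that brightness range had a median of 0.10 (-0.24 to 0.29) and do not show a brighter reading by themselves. Those with a mean log2 intensity between 7 and 11 had a median of -0.18. A larger rise of abundant transcripts in the treated cells was not tested apart from an intensity-dependent difference between the arrays and stays open.

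Heart muscle markers rose and endothelial markers fell. A lower share of sorted progenitors that raised all other types alike would not give an endothelial median of -0.36 (-0.40 to -0.34 with an array left out) beside the heart median of 0.46. These medians are the pattern itself, so they are no separate test. A lower share with an uneven mix of other cell types was not tested and stays open. More heart muscle cells in the retinoic acid samples may have contributed, since 10 heart muscle genes outside the list had a median 0.15 above that of all genes (0.11 to 0.18 with an array left out), although only 4 of them rose and none was bright enough for the test to argue against it. Fewer endothelial cells may have contributed too, since 10 endothelial genes outside the list had a median of -0.21 against all genes (-0.23 to -0.18 with an array left out), although only 2 of them fell. A change of these genes within the sorted cells would give the same values and stays open, as does any effect of retinoic acid on the vessels and heart of the embryo.

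Of the 33 measured genes that the files name as histone cluster genes 24 rose and 0 fell, with a median of 0.33, while in a wider set of 52 histone genes, which holds these, 34 rose and 1, H2az2l2, fell by 1.24. The median correlation between these probe sets within groups was 0.034 (-0.0079 for random genes). It cannot decide whether they read a single shared transcript. The spread within groups was small for genes at large (median SD 0.07 in control and 0.08 in retinoic acid), and no probe sets known to share a transcript were compared. The intensity-dependent difference is argued against as the whole cause, because after cyclic loess the median was 0.17, above 100% of 10000 random lists matched on brightness (the upper end of their central range lay at 0.05), although 12 genes rather than 24 then passed. That median was known when this test was chosen, and it replaced a simpler threshold of 0.1. More cells in S phase may contribute but cannot be told apart, since the S phase list stood 0.153 above all genes in the deposited values and 0.039 after cyclic loess, a value added to this test after it was seen.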

How the results depend on the processing

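Cyclic loess, leaving out histone genes, the lists without marker genes and the lists after median centring were chosen after the data were seen. The gene count moved by less than 1.5 times from 1900 with an intensity trend (1966), a robust prior (1893), the dim filter (2211), the mean of probe sets (1891), array weights (2216), every probe set tested (1547), quantile normalization (1689, 1361 of them shared), median centring (1414, 1408 shared), cyclic loess (1551, 1209 shared) and without histones (1858). Of the 97 called genes that are named, 92 kept their call after quantile normalization, 90 after cyclic loess, 87 after median centring, 53 after centring on spike-in subgroup B and 77 with each array left out in turn. Whether the replicate numbers pair the samples could not be settled with 3 arrays per group. After group means were removed, arrays of the same number correlated at -0.11, 0.24 and 0.24, and those of different numbers at -0.38 to 0.20. A block on the replicate numbers gave 2368 genes and 21 lists. The alternative of taking values from the statistics table was not run, as its means equal those of the value table within 8.0e-09. Dim probe sets limit the size of differences, as the spike-ins below 7 show.

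These counts moved, and unless a stricter test explains it the cause was not tested. Genes lower numbered 638 after quantile normalization and 251 after median centring. Centring on spike-in subgroup B gave 360 genes, 337 higher and 23 lower. The subgroup B medians had an SD between replicates of 0.15, against a median SD of genes of 0.07 in control and 0.08 in retinoic acid. Subtracting them brought that spread into every gene. With a 1.5-fold threshold 100 passed, 75 and 25, and without shrinkage, which leaves 4 degrees of freedom, 21 passed, 15 and 6. Cyclic loess gave 855 higher and 696 lower, and 12 lists, and an estimated correlation gave 2 lists. In the brighter part of the spike-in transcripts the medians of A and B were -1.40 and -0.16. With an array left out, genes ran from 1186 to 1523, those higher from 894 to 1208, those lower from 251 to 348, lists from 16 to 21, and the spike-in medians from -0.70 to -0.30 for A, -0.11 to 0.05 for B, 0.04 to 0.32 for C and 0.17 to 0.56 for D.

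Signs turned for results that did not pass the test before or after, with adjusted p of 0.0516 or more by limma, and the cause was not tested. Among genes, the log2 differences that turned were Gli2 -0.0034, Gli3 -0.048 and Tgfb2 -0.017 after quantile normalization and Gli2 -0.0082, Gli3 -0.064 and Tgfb2 -0.026 after cyclic loess. They were Gli1 0.053, Nr2f2 0.0052, Rarb 0.069, Tgfb3 0.076, Tgfbr1 0.054 and Zic4 0.084 after centring on spike-in subgroup B, and Tgfb2 -0.022 with array weights. For genes that turned with an array left out the ranges were Gli1 -0.11 to 0.031, Gli2 -0.0095 to 0.10, Rarb -0.11 to 0.017, Tgfb2 -0.086 to 0.11, Tgfb3 -0.064 to 0.0081, Tgfbr1 -0.092 to 0.0064 and Zic4 -0.056 to 0.022. The directions of lists, which compare with all other genes, turned at these medians. Without dim genes they were retinoid synthesis 0.027, Wnt 0.055 and leukocytes 0.050. After quantile normalization they were retinoid synthesis 0.028, Wnt 0.043, neurogenesis 0.035, forebrain 0.092, G2 and M phase -0.0044 and p53 targets 0.026. After cyclic loess they were retinoid synthesis 0.022, neurogenesis 0.024, forebrain 0.089, G2 and M phase -0.023, p53 targets 0.010 and the unfolded protein response -0.0085. Without marker genes they were Wnt 0.055 and hindbrain 0.037. For lists that turned with an array left out the medians ranged as Wnt 0.041 to 0.094, forebrain 0.025 to 0.088, hindbrain 0.012 to 0.088, leukocytes 0.046 to 0.12, p53 targets -0.011 to 0.057 and retinoid synthesis 0.020 to 0.057. Fry, which tests a list against no change, pointed up where camera pointed down for neurogenesis 0.020, forebrain 0.082, hindbrain 0.024 and p53 targets 0.050, which is a different question and not a turn of the same comparison.

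The real grouping was 1 of the 10 splits of the 6 arrays, and 10 splits cannot give a share under 0.1. It gave 1900 genes by limma against at most 0 in the others, and 19 lists against at most 12, where again 1 split reached the real count.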

Other observations

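The ribosomal, mitochondrial and immediate early lists were drawn up after results were seen, the last after Nr4a1, Btg2 and Egr2 had been noticed, and its test was written before the members it measures were seen.

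Many ribosomal protein genes and genes of the mitochondrial genome rose. Of 69 ribosomal protein genes 41 rose and 1 fell by limma, with a median of 0.27, and of 10 mitochondrially encoded genes, which encode proteins of the respiratory chain, 9 rose and 0 fell, with a median of 0.45. With an estimated correlation camera in limma gave unadjusted p = 0.0261 and p = 0.0539 for these lists, and p = 0.243 and p = 0.333 after cyclic loess. Most of these calls ended after cyclic loess, where 9 ribosomal genes rose and 1 fell, with a median of 0.06, and 1 mitochondrial gene rose, with a median of 0.13.

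Immediate early genes, which respond to many stimuli within minutes, rose in 18 of 37 and fell in 1. Among those not seen when the list was written, 13 of 32 rose and 1 fell. Of 5 members picked after their values were seen, Egr3 rose by 0.76 (SE 0.07), Ccn1 by 0.71 (SE 0.07), Egr1 by 0.57 (SE 0.07), Arc by 0.54 (SE 0.07) and Fos by 0.34 (SE 0.07). A response to cell dissociation and sorting that differed in degree between the groups may have contributed, since the unseen members had a median of 0.174 (0.148 to 0.216 with an array left out). After cyclic loess that median was 0.04, with a camera p of 2.7e-04 and p = 0.129 with an estimated correlation in limma. A response to retinoic acid would give the same values and stays open.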
